A study of Homo sapiens with 14 samples.

How the data were processed

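RNA was measured in 6 libraries labelled BxPC-3 (3 shControl, 3 shHDAC5) and GATA1 binding in 8 PANC-1 samples (2 immunoprecipitations and 2 inputs for each of shControl and shHDAC5), all at day 3. Samples were grouped by the treatment and antibody in their labels. The RNA file holds whole-number read counts per Ensembl gene, deposited by the authors without normalization. The submitters' processing notes name FastQC 0.11.9, fastp 0.23.2, featureCounts 2.0.1, deepTools 3.5.0, MACS2 2.2.7.1 and the build hg38, without roles. The aligner, the annotation release and the strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes can share or lose reads. Each peak list gives the authors' fold enrichment over the caller's background as a ratio per peak, and −log10 p and −log10 q per peak, as deposited. The labels tie each list to 2 immunoprecipitations and 2 inputs; whether these were pooled is not given in the sources used here. The lowest −log10 p in the lists was 1.30 and 1.31.

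The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. Gene symbols were found for 61369 of 61541 gene IDs, and 2 entries of the gene lists, SOD2 and an older name of RIGI, had no match. Genes passing edgeR's filter by group were scaled by TMM and tested with edgeR's quasi-likelihood test on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM were computed by edgeR over TMM-scaled library sizes, and a standard error is the log2 fold change over the square root of its F statistic. Folds against a group without counts use 3 counts over the group, and intervals on counts and shares are 95% exact binomial ones that cover counting error only. The total counts were 16530058, 15179758 and 17854340 for shControl replicates 1, 2 and 3 and 15935649, 16388744 and 16889876 for shHDAC5. On simulated counts with these depths, 96 of 100 genes changed by 2-fold and 69 of 100 changed by 1.25-fold were recovered among 16612 tested, with 6 false calls, and DESeq2 recovered 139 of the 200. Only these 200 genes were changed in the simulation, with a common dispersion. Its rates therefore do not carry over to data in which most genes differ between the groups.

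The 27 gene lists, the tests and the rule for named genes were fixed before the data were examined. Named genes are HDAC5, GATA1 and PLA2G4A; the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes with an average log2 CPM of at least 1 and no overlap between groups; up to 4 called members per list with the smallest adjusted p; the 5 genes with the highest fold per peak class; and the 5 called genes per direction with the smallest adjusted p and a peak only in the list labelled shHDAC5. Outside this rule, PTGS2, ALOX5, CCNE1, CDKN1A, GATA2, KRT8, KRT19, EPCAM, CDH1, ESRP1, SMAD4, CDKN2A and ZNF875 were added after the data were examined, and so were the genes induced by histone deacetylase inhibitors. Some genes that meet the rule are not reported here. Lists were compared with other genes by camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated one, adjusted over the lists.

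Peaks on chromosomes 1 to 22, X and Y were compared by overlap of at least 1 bp, with 4 shifts of 10 kb and 20 kb to either side as the background. Gene coordinates came from a RefSeq table of the same assembly that gives no strand, so the planned promoter window was replaced by a summit within 1 kb of either end of a coding gene. A GATA motif search at summits was not run because it needs a genome sequence. Peak classes were joined to RNA by symbol, with two-sided Fisher's exact tests and camera. Alternatives were DESeq2 (which replaced its parametric dispersion trend by a local fit), other scalings, other filters, stricter thresholds, the replicate number as a block, leaving out each library, other peak thresholds, overlaps and windows, and another background for the join. Inputs have no file of their own here and were not analysed.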

Results

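RNA from a human pancreatic cancer cell line labelled BxPC-3 was sequenced in 6 libraries, 3 labelled with a control short hairpin (shControl) and 3 with a hairpin against HDAC5 (shHDAC5), a class IIa histone deacetylase, all at day 3. GATA1, a zinc-finger transcription factor best known from red blood cell development, was immunoprecipitated from PANC-1, another pancreatic cancer line, in 8 samples, with 2 immunoprecipitations and 2 inputs per condition. The series title names arachidonic acid metabolism, GATA1 and cPLA2, the product of PLA2G4A, as the subject of HDAC5 loss. The RNA libraries held between 15179758 and 17854340 counts over 61541 annotated genes. To compare them at equal depth, 15179758 counts were drawn from each with replacement. After that, 24288 to 24335 genes had a count in the libraries labelled shControl and 30799 to 31278 in those labelled shHDAC5. Such draws miss some rare genes: shControl replicate 2, which holds 15179758 counts in all, had 25775 genes with a count before drawing.

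HDAC5 (ENSG00000108840, chromosome 17, 44076753 to 44123641, hg38) was higher in the libraries labelled as its knockdown. Its level was 94.9 ± 2.99 CPM (SD, n = 3) in the libraries labelled shControl and 164 ± 4.44 CPM (SD, n = 3) in those labelled shHDAC5, in counts 1482, 1313 and 1618 against 2737, 2816 and 3026. The log2 fold change was 0.79 with a standard error of 0.0358 (adjusted p = 3.95e-40, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 libraries of the latter group lay above all 3 of the former. The target transcript therefore went against the label, and every direction given here for RNA is between libraries as labelled, not between cells shown to have less or more HDAC5.

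GATA1 and PLA2G4A were both higher in the libraries labelled shHDAC5, in which HDAC5 itself was also higher. GATA1 (ENSG00000102145, chromosome X, 48786590 to 48794311) was near the detection limit, with 0.344 ± 0.093 CPM (SD, n = 3) against 2.85 ± 0.438 CPM (SD, n = 3), and 16 against 149 counts per group. Its log2 fold change was 3.02 with a standard error of 0.349 (adjusted p = 1.43e-13, edgeR's quasi-likelihood test), higher in 3 of 3 libraries. PLA2G4A (ENSG00000116711, chromosome 1, 186828949 to 186988981), the cytosolic phospholipase that releases arachidonic acid from membrane lipids, rose from 24.6 ± 2.48 to 51.7 ± 3.07 CPM (SD, n = 3 each). That is a log2 fold change of 1.06 with a standard error of 0.0632 (adjusted p = 7.01e-31, edgeR's quasi-likelihood test), again in 3 of 3 libraries.

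**Figure D1:**
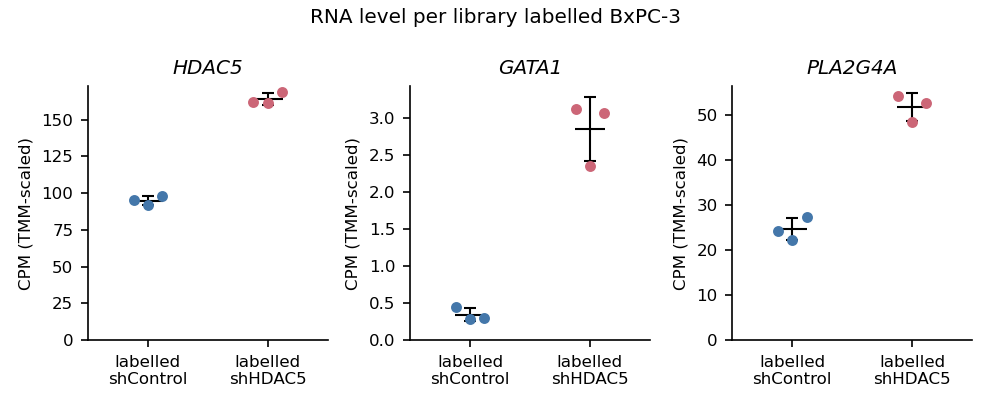
Level of HDAC5, GATA1 and PLA2G4A in each library labelled BxPC-3, in CPM after TMM scaling (vertical axis from 0), by group label (horizontal axis); points are the 3 libraries of a group, the bar is the mean and the whiskers are 1 SD. For each gene all 3 libraries labelled shHDAC5 lie above all 3 labelled shControl, with PLA2G4A means of 24.6 and 51.7 CPM.

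Most of the transcriptome differed between the labels. Of 19181 genes tested, 8597 rose and 7644 fell in the libraries labelled shHDAC5 at an adjusted p under 0.05 (edgeR's quasi-likelihood test), and 5071 and 3846 of these changed by at least 2-fold. CPM values of the groups did not overlap for 84.8% of tested genes, where chance gives 10%. Gene silence was uneven: 366 protein-coding genes had no count in any library labelled shControl and at least 10 counts in each one labelled shHDAC5, while 5 showed the opposite. Within a group, log2 CPM correlated between libraries at 0.992 or more (Pearson, across genes, which are not independent), and between groups at 0.816 or less. No label says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

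The genes with the largest rise had no count in any library labelled shControl, so each fold is a lower bound against 3 counts over that group. CYP4F2, a cytochrome P450 that hydroxylates arachidonic acid and leukotriene B4, reached 150 ± 1.75 CPM (SD, n = 3), at least 2320-fold higher. Reads of CYP4F2 could be shared with its near-identical relatives, as could those of SEMG2, a seminal fluid protein, and FAM153A, whose bounds were 720-fold and 419-fold. MYCT1, TMEM63C and ENPP2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, reached 51.3 ± 2.67, 48.6 ± 1.41 and 47.9 ± 1.69 CPM (SD, n = 3), with bounds of 794-fold, 753-fold and 741-fold. The remaining genes of the 12 were AZGP1, LZTS1, KCNN3, DCLK1, GBP5 and PRUNE2, with bounds from 356-fold for PRUNE2 to 591-fold for AZGP1. KCNN3 encodes a calcium-activated potassium channel, DCLK1 a microtubule-associated kinase and GBP5 an interferon-inducible GTPase.

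Among the genes that fell most, C14orf180, GALNTL6 and RXFP1, the relaxin receptor, had no count in the libraries labelled shHDAC5. They were at least 329-fold, 284-fold and 90.7-fold lower against 3 counts over that group, from 18.9 ± 0.207, 16.3 ± 2.26 and 5.20 ± 0.967 CPM (SD, n = 3). CCR7, a chemokine receptor, and KLF17 kept 2 counts each, which puts them 182-fold (95% counting interval 48.5 to 1470) and 116-fold (32.2 to 978) lower. Several abundant transcripts were nearly lost. SLC16A6, a monocarboxylate transporter, fell from 179 ± 3.51 to 1.96 ± 0.35 CPM (SD, n = 3), and KYNU, the kynureninase of tryptophan breakdown, from 99.8 ± 0.758 to 1.13 ± 0.128 CPM. SLC6A9, a glycine transporter, fell from 80.2 ± 3.66 to 0.86 ± 0.247 CPM, and NUPR1, a stress-induced chromatin protein, from 32.3 ± 1.4 to 0.342 ± 0.144 CPM. ZNF831, VIT and HRCT1 completed the set, with log2 fold changes of -6.30, -6.94 and -7.38.

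The phospholipase A2 enzymes, which free fatty acids from phospholipids, leaned upward. Of 10 tested members 7 rose, 1 fell and 2 did not pass, with a median log2 fold change of 1.31. PLA2G15 (26 ± 1.23 to 130 ± 2.31 CPM), PNPLA8 (51.5 ± 1.12 to 170 ± 3 CPM) and PLA2G12A (26.5 ± 0.341 to 87.0 ± 1.33 CPM; SD, n = 3) rose more than PLA2G4A, while PLAAT3 fell from 71.5 to 40.3 CPM. Compared with all other genes the list did not pass (camera, adjusted p = 0.148 over the 27 lists). Of 31 tested genes of eicosanoid synthesis and breakdown, 20 rose and 10 fell (camera, adjusted p = 0.533). PTGS1, the constitutive cyclooxygenase, fell from 1050 ± 19.9 to 374 ± 9.06 CPM (SD, n = 3), PTGES3 fell from 402 to 228 CPM, and the inducible cyclooxygenase PTGS2 stood at 3.37 and 2.99 CPM without passing. ALOX5, the leukotriene-forming lipoxygenase, rose from 1.81 to 24.4 CPM and CYP4F12 from 0.351 ± 0.126 to 51.2 ± 1.55 CPM. Of 9 prostanoid and leukotriene receptors and transporters, 6 rose and 3 fell (camera, adjusted p = 0.626), with PTGER4, a prostaglandin E2 receptor, rising from 5.73 ± 1.4 to 34.1 ± 0.231 CPM, PTGER2 from 0.255 to 3.68 CPM, and the exporter ABCC4 falling from 62.2 to 33.5 CPM.

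Lipid synthesis genes moved both ways. Of 22 genes for synthesis, uptake and esterification of polyunsaturated fatty acids, 12 rose and 8 fell. FADS1, the delta-5 desaturase that makes arachidonic acid, fell from 473 ± 8.14 to 170 ± 3.2 CPM (SD, n = 3), while MBOAT2 rose from 31.7 to 116 CPM and the fatty acyl-CoA ligase ACSL1 from 10.2 to 37.7 CPM. Of 18 fatty acid synthesis genes, 10 rose and 8 fell, with SCD, the stearoyl-CoA desaturase, falling from 1650 ± 25.7 to 674 ± 7.46 CPM and GPAM, which starts glycerolipid synthesis, rising from 26.6 to 134 CPM. Of 24 cholesterol genes, 14 rose and 8 fell, with HMGCS1, an early enzyme of the pathway, rising from 171 ± 4.93 to 579 ± 1.95 CPM. None of these 3 lists passed against other genes (camera, adjusted p = 0.626, 0.900 and 0.626).

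Proliferation genes fell together. None of 36 tested members rose, 35 fell and CCNE1 did not pass, with a median log2 fold change of -2.06. MKI67, the cycling-cell antigen, fell from 448 ± 25.2 to 72.6 ± 0.636 CPM (SD, n = 3), TOP2A from 914 ± 15.3 to 224 ± 2.37 CPM, CENPF from 469 ± 16 to 90.6 ± 3.36 CPM, and the replication helicase subunit MCM7 from 375 ± 5.69 to 67.4 ± 3.5 CPM. The list passed against other genes with the preset correlation (camera, adjusted p = 1.38e-11) but not with an estimated one (adjusted p = 0.266 with an estimated correlation). MYC, a driver of cell growth, fell from 558 ± 5.67 to 34.2 ± 1.43 CPM. Of 19 p53 targets 7 rose and 8 fell (camera, adjusted p = 0.889), among them the death receptor FAS, which fell from 19.3 to 1.82 CPM, and the cell cycle inhibitor CDKN1A, which rose from 159 to 224 CPM.

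Of 27 immediate early and stress genes, 20 rose and 6 fell, short of the threshold against other genes (camera, adjusted p = 0.061). NR4A1, an orphan nuclear receptor, rose from 135 ± 3.12 to 1280 ± 8.28 CPM (SD, n = 3) and the AP-1 subunit JUN from 14.6 ± 0.499 to 179 ± 3.4 CPM, while the small heat shock protein HSPB1 fell from 238 to 40.8 CPM. Of 30 genes of the unfolded protein and integrated stress responses, 10 rose and 15 fell (camera, adjusted p = 0.576). The amino acid transporter subunits SLC7A5 and SLC3A2 fell from 1400 ± 27.6 to 275 ± 8.36 CPM and from 505 ± 9.18 to 91.9 ± 1.41 CPM, and HSPA5, the chaperone of the endoplasmic reticulum, rose from 718 ± 9.62 to 2420 ± 32 CPM. Of 31 glycolysis and hypoxia genes, 14 rose and 15 fell (camera, adjusted p = 0.626), with ENO1 falling from 3200 ± 41.1 to 1230 ± 12.6 CPM. Of 19 ferroptosis and glutathione genes, 6 rose and 12 fell (camera, adjusted p = 0.605). The cystine transporter SLC7A11 fell from 115 ± 3.4 to 4.89 ± 0.652 CPM and NQO1 from 138 to 12 CPM, whereas TXNRD1 rose from 489 to 1090 CPM.

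Interferon response genes split, with 17 of 28 higher and 10 lower (camera, adjusted p = 0.626). IFI6, an interferon-induced mitochondrial protein, rose from 16.9 ± 1.64 to 94.1 ± 3.99 CPM (SD, n = 3), while IFITM3, which blocks virus entry, fell from 194 ± 8.69 to 18.8 ± 1.49 CPM and IFI35 from 86.1 to 2.18 CPM. Of 20 NF-kappaB and cytokine genes, 10 rose and 9 fell (camera, adjusted p = 0.900). BIRC3, an inhibitor of apoptosis, rose from 15.9 ± 1.3 to 570 ± 16.9 CPM, and NFKB2 rose from 114 to 300 CPM as NFKB1 fell from 50.5 to 2.75 CPM.

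Cell identity genes showed mixed changes between the labels and, in all 6 libraries, levels unusual for the named line. Of 20 tested epithelial genes, 7 rose and 10 fell (camera, adjusted p = 0.626), with the keratin KRT7 falling from 371 ± 9.72 to 25.3 ± 0.445 CPM (SD, n = 3) and the desmosomal DSP from 538 to 150 CPM. In every library 11 of the 26 list members were under 3 CPM, among them KRT19, EPCAM and CDH1, at 0.0215, 1.84 and 1.43 CPM under shControl labels, while KRT8 stood at 717 and 1010 CPM. SMAD4 and CDKN2A, genes known to be deleted in BxPC-3 and looked up outside the fixed lists once the data were in hand, stood at 49.6 ± 2.59 and 46.8 ± 0.789 CPM and at 149 ± 4.78 and 13.7 ± 0.648 CPM. The labels' cell line is therefore not taken as established. Of 28 mesenchymal genes, 13 rose and 15 fell (camera, adjusted p = 0.826). The matricellular CCN2 and CCN1, targets of YAP signalling, rose from 105 ± 2.12 to 1160 ± 10.1 CPM and from 99.4 ± 4.51 to 1010 ± 11.6 CPM, while the receptor kinase AXL fell from 158 to 25.3 CPM. Of 13 basal-like subtype genes, 10 rose and 3 fell, with a median log2 fold change of 2.82 (camera, adjusted p = 0.148). AREG, an EGF receptor ligand, rose from 9.90 ± 0.369 to 651 ± 17.1 CPM and KRT17 from 824 ± 12.4 to 2130 ± 26.1 CPM, and TNS4 fell from 171 to 11.2 CPM. Of 7 classical subtype genes, 4 rose and 3 fell (camera, adjusted p = 0.697), with CEACAM6, whose reads could be shared with relatives, at least 130-fold higher and KRT20 down from 4.12 to 0.0967 CPM.

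Of 16 histone deacetylases and class IIa partners, 8 rose and 8 fell (camera, adjusted p = 0.974). HDAC3 rose from 53.8 ± 2.22 to 171 ± 4.38 CPM (SD, n = 3) alongside HDAC5, while the class IIa member HDAC7 fell from 93.6 ± 3.16 to 18 ± 1.21 CPM and the co-repressor NCOR1 from 255 ± 8.09 to 69.7 ± 0.667 CPM. Of 11 GATA factors and cofactors, 7 rose and 3 fell (camera, adjusted p = 0.626). GATA2 did not pass at 91.8 and 94.3 CPM, far above GATA1 in either group, GATA6 fell from 11.3 to 4.70 CPM and the cofactor LMO4 rose from 10.9 to 25.9 CPM. Of 9 tested erythroid targets of GATA1, 5 rose and 4 fell (camera, adjusted p = 0.826), with HBB at least 79.4-fold higher at 5.13 ± 0.986 CPM and NFE2 lower, from 10.1 to 0.964 CPM.

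Markers of other cells and of RNA quality changed in either direction, and as lists only the ribosomal proteins passed. Of 8 fibroblast markers 3 rose and 4 fell (camera, adjusted p = 0.626), of 5 endothelial markers 1 rose and 3 fell (adjusted p = 0.626), and of 6 leukocyte markers 2 rose and 2 fell (adjusted p = 0.974). COL6A3, a collagen of fibroblasts, rose from 0.131 to 32.4 CPM while PDGFRB fell from 29.6 to 6.59 CPM. Of 13 mitochondrially encoded mRNAs 6 rose and 7 fell (camera, adjusted p = 0.974), taking 4.79% to 4.82% of counts under shControl labels and 5.48% to 5.63% under shHDAC5 labels. Of 17 replication-dependent histone mRNAs 9 rose and 4 fell (camera, adjusted p = 0.626), and of 27 cytosolic ribosomal protein mRNAs 4 rose and 20 fell. The ribosomal list passed with the preset correlation (camera, adjusted p = 0.0104; adjusted p = 0.776 with an estimated correlation) but not with upper-quartile factors or total counts (camera, adjusted p = 0.0777 and 0.143). In it RPL13A fell from 1940 ± 48.9 to 919 ± 9.99 CPM (SD, n = 3). In each of the 27 lists, the counts adjusted over the list alone equalled those over all genes tested. Median, mean and test differed in sign for the fibroblast list, with a median of -0.35 and a mean of 0.50, and for the mesenchymal list, with a median of -0.27 and a mean of 0.55. They also did for the endothelial, leukocyte, mitochondrial and histone deacetylase lists.

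**Figure D2:**
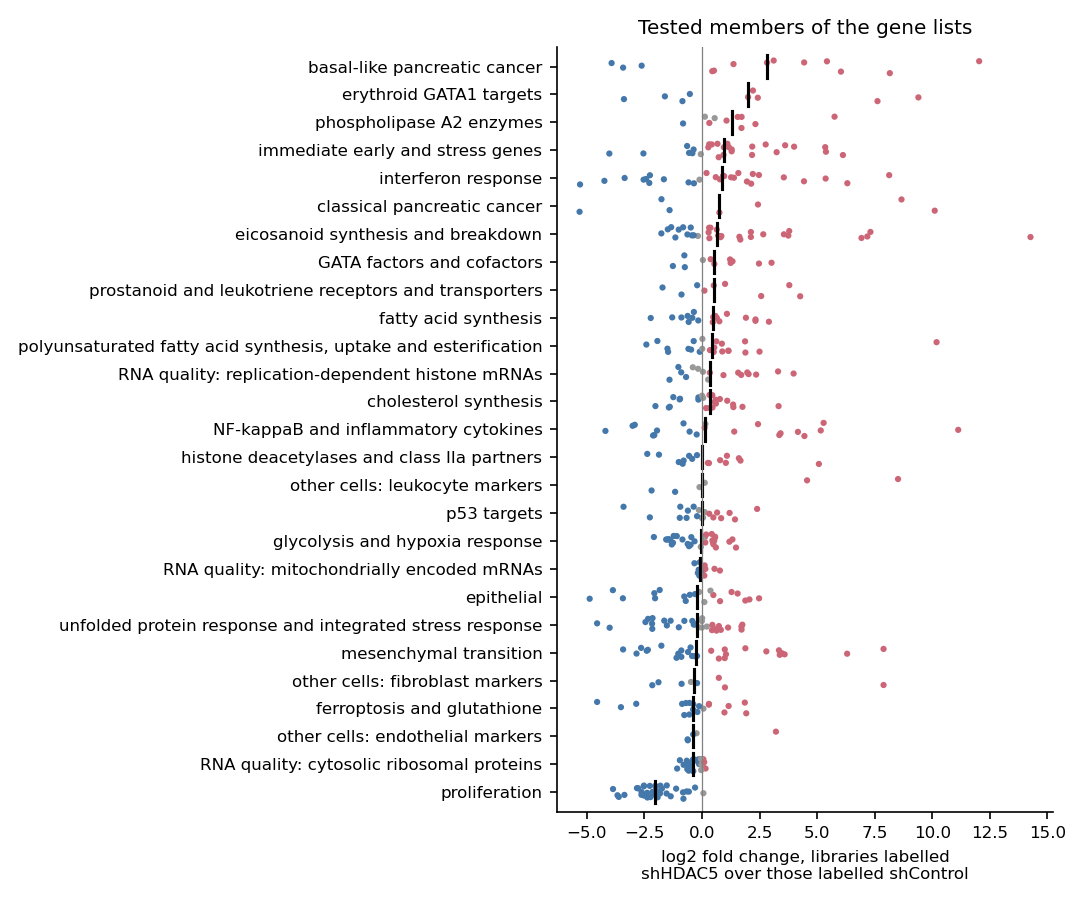
Log2 fold change between libraries labelled shHDAC5 and shControl (horizontal axis) of each tested member of the 27 gene lists (vertical axis, ordered by median); red points rose and blue points fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test), grey points did not pass, and black ticks are list medians. The proliferation list lies lowest, with a median of -2.06 and no member that rose.

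For GATA1 in PANC-1 the series holds 1 peak list per condition, so no difference between conditions could be tested against replicates. The list labelled shHDAC5 held 249139 peaks on chromosomes 1 to 22, X and Y and the list labelled shControl 121070. Peak names inside the lists contradicted the labels: those in the list labelled shControl began with GATA1-SAHA-IP, and those in the list labelled shHDAC5 with GATA1-NC-IP, the name the sample titles give to the control. The conditions compared, and the direction of any difference between the lists, thus depend on whether labels or peak names are right. Neither peak name holds shHDAC5, so if the names are right neither list is one of HDAC5 knockdown. Most peaks were weak. The authors' q was at most 0.05 for 6176 peaks (5.10%) of the list labelled shControl and 1045 (0.419%) of the list labelled shHDAC5, a threshold chosen after seeing the data, and the longer list became the shorter one. At a fold enrichment of at least 5, as given by the authors, 587 and 86 peaks were left. Of the list labelled shControl 11.6% overlapped the other list by at least 1 bp (95% exact interval 11.4% to 11.8%), against 7.94% when one list was shifted. Of the list labelled shHDAC5 5.54% overlapped (5.45% to 5.63%), against 3.79% after the shift.

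**Figure D3:**
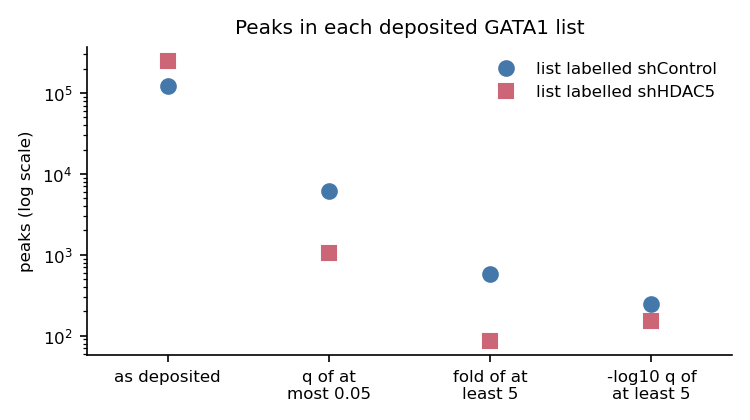
Number of peaks on chromosomes 1 to 22, X and Y (vertical axis, log scale) in the GATA1 lists labelled shControl (circles) and shHDAC5 (squares), as deposited and at 3 stricter thresholds (horizontal axis). The list labelled shHDAC5 has more peaks as deposited, 249139 against 121070, and fewer at each stricter threshold.

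Peaks lay nearer to gene ends in the list labelled shControl. In it, 11.4% of summits were within 1 kb of either end of a protein-coding gene, against 5.61% after shifting, whereas in the list labelled shHDAC5 the shares were 2.98% and 2.69%. At a q of at most 0.05 they were 20.4% against 6.68% and 4.78% against 2.82% and at a −log10 q of at least 5 they were 18% against 8.71% and 1.32% against 1.49%. Of 19974 coding genes, 3957 had such a peak in both lists, 2836 only in the list labelled shHDAC5 and 6474 only in the list labelled shControl. Among genes with a peak in both lists, the highest fold in either was at TAF11L3 (chromosome 5, 17518367 to 17518963), a member of a repeated gene family, with 9.60 in the list labelled shControl and 5.17 in the other. NCAPD3 and VPS26B, which share a peak, PPP1R3G and MFSD6 came next, each with the higher fold in the list labelled shControl. The highest in the list labelled shHDAC5 only were at MRPS21 (5.13), PLAAT3 (5.11), a phospholipase A2, CACUL1, AGPAT4 and CEACAM4. For the list labelled shControl only they were at KCNG2 (6.69), AAMDC, SIGIRR, CALCOCO2 and ELOB (6.04). The strongest peak by p of the list labelled shControl was on chromosome 19 at 37293266 to 37294811, 18321 bp from ZNF875. Several others among its strongest lay close together on that chromosome, between 39472118 and 39892473. The strongest of the list labelled shHDAC5 was on chromosome 17 at 23016186 to 23016528, 310749 bp from the nearest annotated gene. Its next strongest, down to a −log10 p of 54.8, all lay at least 69837 bp from any annotated gene, several close together on chromosome 16. These clustered peaks of either list are part of the set at a −log10 q of at least 5. The latter list had 5.96% of summits in any annotated gene at a −log10 q of at least 5, against 58.2% as deposited. In the list labelled shControl these shares were 73.0% and 69.7%. Inputs were not analysed, so whether the strongest peaks reflect GATA1 binding was not tested.

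At the genes of the series title, peaks were weak and none reached a q of 0.05. PLA2G4A and 10 kb on either side held 28 peaks in the list labelled shHDAC5, the highest with a fold of 3.29, and none in the list labelled shControl. From the density of peaks within 1 Mb, 17.4 and 2.42 would be found there. GATA1 held 7 peaks in the list labelled shHDAC5 and 1 in the list labelled shControl (2.10 and 1.44 from the density), and HDAC5 4 and 11 (6.70 and 5.88).

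**Figure D4:**
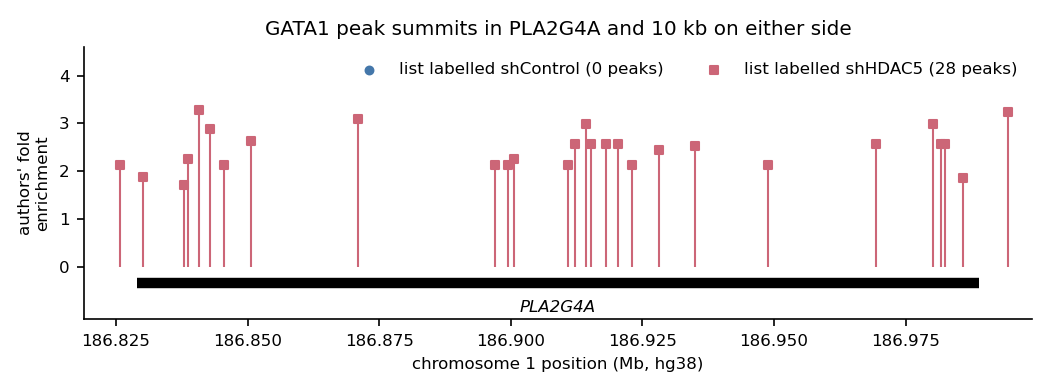
Summits of the 28 peaks of the list labelled shHDAC5 (squares) at PLA2G4A (black bar) and 10 kb on either side, by chromosome 1 position in Mb on hg38 (horizontal axis) and the authors' fold enrichment (vertical axis); the list labelled shControl has 0 peaks there. The highest fold is 3.29, and no peak has a q of at most 0.05.

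Peak class in PANC-1 was set against the RNA change in the libraries labelled BxPC-3, over 13707 coding genes tested in RNA. Of 1747 genes with a gene-end peak only in the list labelled shHDAC5, 48.5% rose and 39.9% fell, against 43.5% and 45.0% of other genes. The odds ratio of rising was 1.22 (95% interval 1.11 to 1.36; adjusted p = 0.000263 over the 3 classes, two-sided Fisher's exact test, in which genes are not replicates). The 2836 coding genes of this class shrank to 33 at a q of at most 0.05 and to 0 at a −log10 q of at least 5. The class was not joined to RNA at either threshold, so its odds ratio rests on weak peaks. Of 5011 genes with a peak only in the list labelled shControl, 42.1% rose and 46.6% fell, with an odds ratio of rising of 0.880 (0.820 to 0.945; adjusted p = 0.000568, same test). At a −log10 q of at least 5 that direction turned and did not pass, with a log2 odds ratio of rising of 0.93 over 30 genes (p = 0.0971, two-sided Fisher's exact test). Of 3042 genes with a peak in both, 43.4% rose and 45.4% fell, with an odds ratio of 0.964 (0.888 to 1.05; adjusted p = 0.374, same test). None of the 3 classes passed as a set (camera, adjusted p = 0.628, 0.628 and 0.828), nor with an estimated correlation (adjusted p = 0.633, 0.800 and 0.854 with an estimated correlation).

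Genes changed in RNA with a gene-end peak only in the list labelled shHDAC5 were named by the smallest adjusted p, 5 in each direction, so their large changes follow from that choice. DHRS2, a short-chain dehydrogenase, rose from 0.217 ± 0.101 to 444 ± 6.19 CPM (SD, n = 3), ANKRD1, a YAP target, from 0.435 to 272 CPM, PEG10 from 201 to 1348 CPM, RIMKLB from 261 to 1550 CPM and ACTBL2 from 0.105 to 179 CPM. MYC, CUL4A, RNF182, MUC13 and MARCOL fell, with CUL4A, a ubiquitin ligase scaffold, going from 1056 ± 5.07 to 95.3 ± 3.9 CPM and the mucin MUC13 from 266 to 17.2 CPM. The authors' fold enrichment at these 10 genes lay between 1.71 for DHRS2 and 2.65 for MYC.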

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

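The thresholds of a q of at most 0.05 and the join within 10 groups of average expression were chosen after seeing the data; the other alternatives were not. The count of 16241 called genes stayed within 1.5 times under every alternative except a fold of at least 2, which by its construction left 8917, of which 5071 rose and 3846 fell; HDAC5, at a log2 fold change of 0.79, also missed that minimum. Leaving out each library gave 16173 to 16567 called genes, 8499 to 8883 higher and 7622 to 7718 lower, and a HDAC5 log2 fold change of 0.75 to 0.79. Scaling by upper quartile or total counts moved the median log2 fold change by 0.140 and 0.184, and the genes higher and lower from 8597 and 7644 to 9480 and 6843 and to 9727 and 6596; DESeq2 gave 10617 and 7695. Replicate numbers are shared by the groups, but deviations of same-numbered libraries correlated at -0.0126, 0.00258 and 0.00593, so the numbers were not taken as pairs; with the replicate number as a block 16072 genes were called, 8514 higher and 7558 lower, HDAC5 stood at 0.79, and 2 lists passed. Of 1716 values of named genes under alternatives, 1714 kept direction and side of the threshold; with total counts MT-CO3 went from -0.18 to 0.002985 and ERG no longer passed. Of the 27 lists 2 passed; 0 did with an estimated correlation, and 1, proliferation, did with upper-quartile factors or total counts. The log2 ratio of peak number, 1.04, became -0.69 at a −log10 q of at least 5 (244 and 151 peaks under shControl and shHDAC5 labels; overlaps of 5.74% and 9.27%), -2.77 at a fold of at least 5 (587 and 86; 0.341% and 2.33%) and -2.56 at a q of at most 0.05 (6176 and 1045; 1.10% and 6.51%); the cause was not tested. Overlaps were 2.34% and 2.33% for the top 10000 peaks (0.935% and 0.918% after shifting), 4.72% and 2.29% at a reciprocal 50% (2.68% and 1.3%) and 6.74% and 3.27% for summits within 200 bp (4.11% and 1.99%); after shifting they were 0.211% and 1.15% at a q of at most 0.05, so as a ratio to the shift the overlap did not fall. Genes with a gene-end peak in both lists numbered 8799 within 3 kb and 1769 within 500 bp, and those in the list labelled shControl only 4267 within 3 kb. At a −log10 q of at least 5 there were 2, 0 and 39 such genes in both, the shHDAC5-labelled only and the shControl-labelled only, and at a q of at most 0.05 18, 33 and 1284. With a −log10 q of at least 5, 30 genes of the last class were tested in RNA and their log2 odds turned to 0.93 for rising and -1.14 for falling (p = 0.0971 and 0.0646, Fisher's exact test); the other join results kept side of the threshold, and direction except for rising with a peak in both lists, which did not pass and was near 0 within 3 kb. No join value could be had for the other classes at that threshold, and the motif windows were not run. At these depths genes under about 10 counts per library, GATA1 among them in the libraries labelled shControl, are known only roughly.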

Other observations

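The tests in this part were set against these patterns only after the results were seen, although the scalings were planned before. Among 14 genes written down as commonly induced by histone deacetylase inhibitors, 10 were higher and 4 lower in the libraries labelled shHDAC5 (edgeR's quasi-likelihood test), where 44.8% of all tested genes were higher. The neuronal genes SYP and TUBB3 rose from 1.24 ± 0.241 to 29.3 ± 0.756 CPM (SD, n = 3) and from 4.74 to 35.3 CPM, CLU, a secreted chaperone, from 743 ± 17.5 to 2700 ± 31.4 CPM, and SERPINI1 from 21.2 to 131 CPM. TXNIP, an inhibitor of thioredoxin, fell from 940 to 676 CPM.

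HDAC5 was higher where the label says it was knocked down. None of 4 scalings removed this: the lowest log2 fold change, 0.788 with a standard error of 0.0358, was that of TMM itself. RLE, upper-quartile and total-count scaling gave 0.819, 0.929 and 0.972. All 4 set a gene against the other counts of its library, so they cannot tell whether HDAC5 rose per cell. An exchange of only 1 or 2 libraries between the groups is argued against by the correlations, at most 0.816 between groups and at least 0.992 within them. An exchange of all labels stays open, since the value of -0.788 after the exchange is only the same value with its sign turned and does not test it. No biological explanation was tested.

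SMAD4 and CDKN2A, deleted in BxPC-3, were expressed in all 6 libraries, while KRT19, EPCAM, CDH1 and ESRP1 were low and other epithelial genes, such as KRT8 at 717 and 1010 CPM, were not. A candidate explanation is a cell line other than BxPC-3: the lowest level of either gene in any library was 13.1 CPM. BxPC-3 mixed with other cells is argued against by the 4 low genes, of which the highest level in any library was 2.40 CPM. Loss of reads to near-identical copies would touch few genes, whereas 11 of 26 epithelial list members were under 3 CPM in every library. No biological explanation was tested.

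Many genes without counts under shControl labels were detected under shHDAC5 labels. The 10309 genes of at least 1 kb without counts under shControl labels held 163620 counts under shHDAC5 labels. Spread evenly along gene length, as by genomic DNA, these counts would leave 0.0595% of the genes without any, but 44.5% had none. This argues against an even background as the source of all these counts. A weaker even background beside expressed genes was not tested. Different cell lines under the labels of the groups would be expected to silence genes in either direction, and 5 coding genes were silent the other way against 366; this does not exclude it, so it cannot be told apart from an effect of treatment. A further hypothesis is inhibition of histone deacetylase activity, since SAHA, in the peak names, is a common abbreviation of such an inhibitor, although those names stand in the list labelled shControl and in another cell line; 10 of 14 genes commonly induced by it were higher (p = 0.0589, two-sided Fisher's exact test), but the list was written after values were seen, and TXNIP went the other way, so this too may or may not hold.

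The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 16241 genes and the highest other 0, with 1 split as large, and 2 lists against 2, with 5 splits as large. Each other split mixes the labels, which moves the difference between them into the spread within its groups. The 0 genes called there therefore carry no information of their own. For the peak classes −log10 of the camera p was 0.649 in the real split and 0.711 in the highest other for peaks only in the list labelled shHDAC5 (3 splits as large), 0.082 and 0.148 for both lists (6 splits), and 0.378 and 0.398 for the list labelled shControl only (2 splits).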
